A study of Caenorhabditis elegans with 2 samples.

How the data were processed

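Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans carrying a transgene that encodes ZIM-3 with a C-terminal GFP-FLAG tag, and the tagged protein was precipitated with an antibody against GFP. The animals were young adults of mixed sex, collected 54.5 h after synchronised release from L1 arrest. There were 2 biological replicates of this 1 group, and no control or untagged sample was analysed here. With a single group, no comparison between conditions was possible, and the tests set peaks or genes against positions in the genome, other genes, flanking sequence, lower-ranked regions or peaks on other chromosomes.

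For each replicate the authors deposited a list of 30000 regions (peaks and background together) intended as input to the irreproducible discovery rate (IDR) procedure, which ranks regions by how well replicates reproduce them. They deposited a list of the same size called on the pooled reads of both replicates, and an optimal IDR-thresholded list derived from these. Per the deposited file descriptions, each list was made with a control library, which was not used here. All lists exist on the ce10 and ce11 assemblies per the labels. The aligner, the peak caller, the IDR threshold and all software versions are not given in the sources used here. The region height is the signal value that the authors deposited. Its scale differed between the lists, so it was used to rank and describe peaks within a list. The −log10 of the q-value, as deposited by the authors, reached one shared ceiling value in 417 of the regions of the pooled list and was not used for ranking. The summit of a region is the authors' deposited offset from its start. Nearly all regions had one fixed width (376 bp for 99.9% of the pooled regions), so summit positions are mostly the centres of fixed intervals. No file gave read counts, so the depth of each library is unknown, and differences in signal between the replicates cannot be related to depth.

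The 906 peaks of the ce11 IDR list were the main material. These peaks were exactly the 906 regions of highest signal in the pooled list. Coordinates are 1-based ce11 positions, which matches the WBcel235 reference sequence and Ensembl release 115 annotation used for genes, biotypes and sequence. The 6 nuclear chromosomes were used. The lists on ce10 served for counts and shares that need no annotation or chromosome length.

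The share of summits on each chromosome was set against its share of assembly length with 2-sided exact binomial tests, adjusted by the Benjamini-Hochberg procedure over the 6 chromosomes. Shares are given with 95% Clopper-Pearson intervals, which cover counting error over peaks only. The median signal on chromosomes I and IV was compared with that on the others by a 2-sided permutation test with 100000 resamples. Summits within 2 Mb of each of the 12 chromosome ends were tested against uniform placement with exact binomial tests. The densest 500 kb window of each chromosome was compared with 10000 uniform placements, 1-sided, where the smallest attainable p was 0.0001 before adjustment. Each summit was assigned to a promoter (within 500 bp of a protein-coding transcription start), another exon, an intron or intergenic sequence, in that order. Proximity within 500 bp to genes of 10 other biotypes was recorded separately. These 14 classes were compared with 1000 uniform placements within the same chromosomes, 2-sided, with a smallest attainable p of 0.002 before adjustment. The 19 gene lists, fixed before the data were examined, were tested with Fisher's exact test, 2-sided, for genes with a summit within 1 kb of their start. The background was all protein-coding genes, or all genes for the list of small RNA biotypes. Several lists follow name patterns, and the chemoreceptor pattern also takes in a few genes with similar names, such as serpins. Summits of different lists were matched within 200 bp. Each 8-mer within 50 bp of a summit, with both strands joined, was compared with 2 windows of the same width centred 500 bp away (Fisher's exact test, 2-sided, adjusted over all 8-mers seen).

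Named genes followed a rule fixed before the data were examined. It took the gene nearest to each of the 25 highest IDR peaks (within 1 kb, with a summit of each replicate within 200 bp), him-8, zim-1, zim-2, zim-3 and unc-119, up to 4 members of each gene list by peak signal, and the gene at the highest peak of the densest window of each chromosome. Genes outside this rule are said to have been chosen after their values were seen. The 12 bp repeat was defined from the data as the 12-mer found near the largest number of summits in the densest window of chromosome IV (ties broken by genome-wide copy number). An array is a run of at least 4 copies with gaps of at most 1 kb, and it was counted as bound when an IDR summit lay within 300 bp.

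The tests were checked on simulated lists of 906 summits. Uniform placement gave any call in 1 of 40 lists for the chromosome, end and window tests each, and in 0 of 10 for gene context and for gene lists. A cluster of 25 summits planted at the left end of IV was called in 40 of 40 lists by both the end and the window test. Planting 50 summits at snoRNA genes or 20 at ribosomal protein genes was recovered in 10 of 10 lists, and an 8-mer planted in 45 windows in 5 of 5. Alternatives varied the assembly, the number of peaks, the replicates used, the distances, the window sizes and the k-mer background. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.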

Results

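ZIM-3 is a zinc finger protein of the meiotic pairing centres of chromosomes I and IV in C. elegans. ChIP-seq against its GFP-tagged form in whole young adults, with 2 biological replicates, gave 906 IDR peaks on the ce11 assembly and 882 on ce10. The signal of the ce11 peaks, in the authors' units, ran from 140.7 to 818.0 with a median of 174.7. Replicate 1 reached a signal of 611.1 and replicate 2 a signal of 239.0. The read depth behind these values is unknown.

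The question that the choice of protein poses is where along the genome ZIM-3-GFP was bound. The 2 highest peaks lay at the left end of chromosome IV. The highest had its summit at IV 195784, in an intron of csn-3, which encodes a subunit of the COP9 signalosome, with a signal of 818.0 and rank 1 in both replicates. The next lay in an intron of tut-1, a gene of tRNA thiolation, at IV 119979, with a signal of 752.2 and ranks 2 and 6 in replicates 1 and 2. In the same region Y38C1AA.1 held the peak of rank 18 at IV 215935, and a peak 37 bp outside Y38C1AA.12, at IV 192219, had rank 23.

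Small non-coding RNA genes accounted for most of the other leading peaks. Of the 25 highest peaks, 13 lay within 500 bp of a tRNA, snoRNA or snRNA gene. The nearest such gene was a snoRNA or snRNA gene in each case. The snoRNA gene C51F7.4 contained the summit at V 12303609 (signal 655.2), and W03C9.9, Y23H5B.10, Y74C9A.6, ZK265.10, T06C12.16 and Y75B12B.12, also snoRNA genes, were nearest to peaks with signals between 430.4 and 515.6. The intronic peaks of pxn-1 (signal 664.8) and cutl-18 (506.8) lay 3 bp and 43 bp from the snoRNA genes ZK994.7 and T03F7.8, which were looked up after the peaks were seen. The peak in the non-coding RNA gene C10C6.11 (signal 429.0) was 53 bp from a snoRNA gene. The snRNA-class genes sls-2.4, which encodes a spliced leader RNA, and R07E5.16 had signals of 499.6 and 417.6. The summit in an intron of ints-8 at I 13463952 (signal 637.6, ranks 7 and 2) was 3 bp from rpr-1, the gene of the RNase P RNA, a neighbour likewise looked up afterwards.

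Protein-coding genes led at the remaining sites. The summit at III 3867563 lay 291 bp upstream of rpl-3, a ribosomal protein gene, with a signal of 648.1. A summit 168 bp upstream of F44E5.4, a heat shock protein gene of the Hsp70 family, had a signal of 558.7. The coding sequence of dos-3 on III contained a summit with a signal of 680.3, and an intron of mdt-26, a Mediator gene, one with 489.8. Summits outside K12H4.5 (462.3), tmem-107 (454.1), set-16 (431.6), a histone methyltransferase gene, and F56G4.6 (421.8) completed the leading 25. The tmem-107 summit was also 107 bp from a snoRNA gene. All 25 had a summit in the list of each replicate, within rank 29 of replicate 1 and rank 61 of replicate 2.

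Chromosomes I and IV did not hold more peaks than their lengths give. Together they carried 279 of 906 summits, 30.8% (95% interval 27.8 to 33.9), against 32.5% of the assembly length (exact binomial p = 0.287). Chromosome III held more summits than its length gives, 18.4% against 13.7% (exact binomial, adjusted p = 0.000267), and chromosome V fewer, 14.2% against 20.9% (adjusted p = 2.2e-06). Chromosome X held 20.5% against 17.7% (exact binomial, adjusted p = 0.0525). It passed the test with summits within 10 kb joined (21.1%, exact binomial, adjusted p = 0.0362), while without replicate 2 its share was 18.1% (adjusted p = 0.873). The median signal was 179.2 on I and IV and 174.5 on the other chromosomes, and the difference of 4.68 did not pass the permutation test over peaks (p = 0.174). The peaks are not independent replicates, so these tests describe this peak list.

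Of the 302 summits within 500 bp of tRNA, snoRNA or snRNA genes, 107 (35.4%) were on X. Among the other 604 summits, X held 13.1%, below its share of length (exact binomial, adjusted p = 0.00552), III held 21.2% and V 15.9%. The share of X thus lay on the other side of its length once summits near these genes were left out, a comparison chosen after the data were seen. Of the annotated tRNA genes, 276 of 612 (45.1%) are on X.

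**Figure D1:**
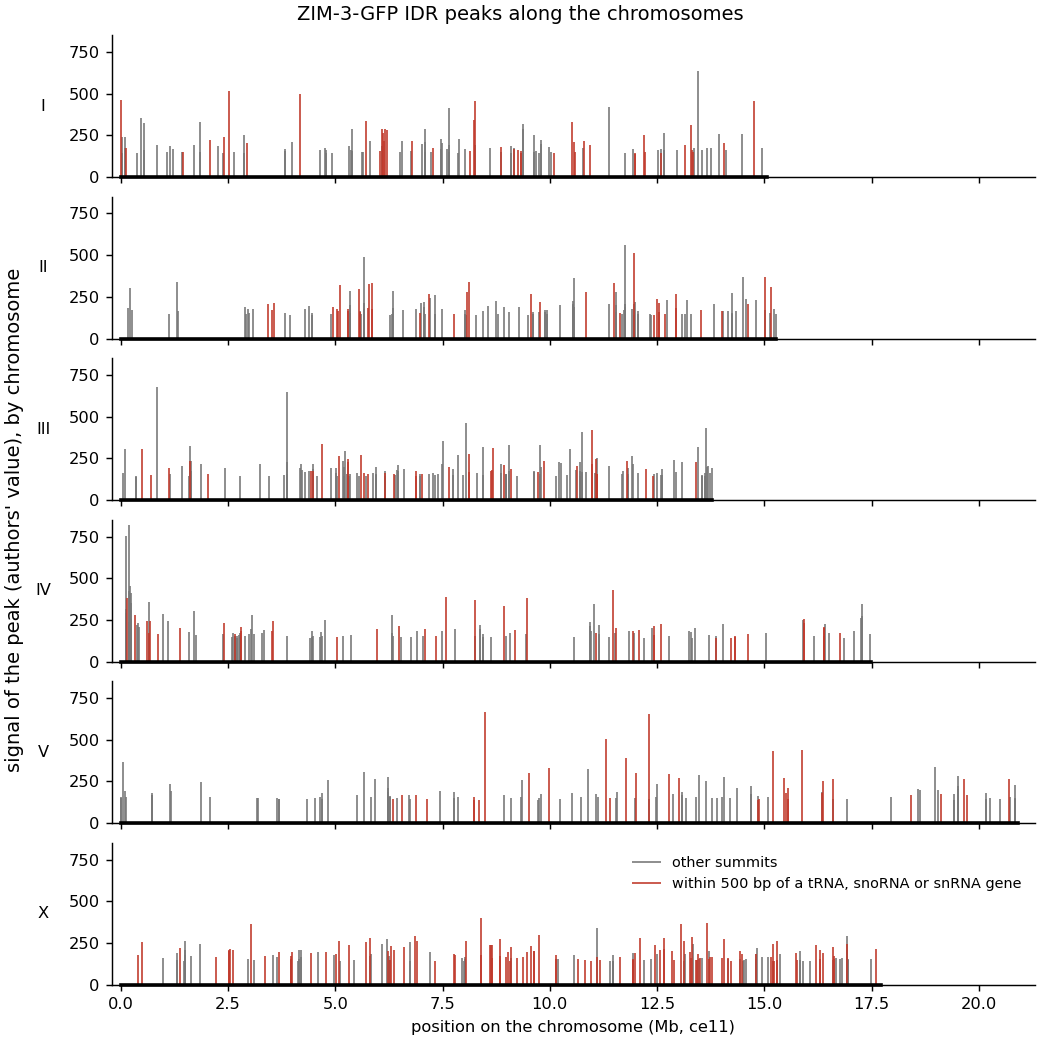
Position (Mb, ce11) and signal (the authors' value) of each of the 906 IDR summits on the 6 chromosomes; black bars give chromosome lengths, and red lines mark the 302 summits within 500 bp of a tRNA, snoRNA or snRNA gene. The 2 highest peaks stand at the left end of IV, and red lines are most frequent on X, with 107 of the 302.

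Pairing centres lie towards one end of each chromosome, which the next comparison addressed. The left end of IV held 32 summits within 2 Mb against 16.8 placed uniformly, a ratio of 1.90 (exact binomial, adjusted p = 0.00294). The left end of II held 6, a ratio of 0.316 with the same adjusted p. This deficit no longer passed without replicate 2 (ratio 0.477, exact binomial, adjusted p = 0.0771), in the higher-signal peaks, without summits near small RNA genes, with summits within 10 kb joined or with ends of 1 Mb, and its adjusted p ran from 0.000143 to 0.124 over the alternatives. The other 10 ends did not pass the test. The right end of I had 15 summits against 17.5 (exact binomial, adjusted p = 0.897). The densest 500 kb window of IV, from 119979 to 619978, held 20 summits. Uniform placement gave a median of 10 and at most 19 (1-sided, n = 147 summits on IV, adjusted p = 0.0006). Before adjustment this p was the smallest that these placements can give. The highest peak of the window was that of csn-3. A window of II from 11484807 held 16 summits (n = 145 summits on II, adjusted p = 0.018), with its highest peak at F44E5.4, and was not called without replicate 2 (15 summits), in the higher-signal peaks (10), with windows of 1 Mb or with summits within 10 kb joined. The densest windows of I, III, V and X did not pass the test, with 10, 15, 9 and 14 summits.

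The summits at the left end of IV lay close together. When summits within 10 kb of each other were joined and counted once, the ratio at this end was 1.41 (exact binomial, adjusted p = 0.411) and no window or end passed its test. Within the window, 12 of the 20 summits lay in introns of tut-1, grld-1, csn-3, Y38C1AA.1, gtf-2H1 and ints-13. grld-1, gtf-2H1 and ints-13, chosen after their values were seen, had peaks of signal up to 289.4, 349.8 and 413.5. gtf-2H1 encodes a TFIIH subunit and ints-13 an Integrator subunit.

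A sequence repeated in these introns was then examined. The 12-mer TTGGTTGAGGCT was chosen for lying within 50 bp of the largest number of the 20 summits in the window, 12 of them, so its presence at summits on IV follows from that choice. It was 1 of 2 tied 12-mers and was taken for its copy number in the genome, so the counts on I may depend on that rule. The reference holds 1002 copies, of which 188 are in the first Mb of IV and 797 on chromosome I beyond 10 Mb, while II, III, V and X hold 1, 10, 1 and 2. On IV the copies were spaced by a median of 20 bp and on I by 211 bp. Copies formed 9 arrays on IV and 74 on I. An IDR summit lay at 7 of the 9 arrays on IV (77.8%) and at 1 of the 74 on I (1.35%). The share on IV is largely set by the choice of the repeat, so the chromosomes are not compared by a test here. The share on I depended on the distances chosen. With summits taken within 1 kb 4 of the 74 counted as bound (5.41%), and with gaps of at most 500 bp 0 of 73, while IV stood at 7 of 9 and 8 of 10. The arrays on IV in tut-1, grld-1, csn-3, Y38C1AA.1 and gtf-2H1 and a pair in ints-13 were bound, and those in tcl-2 and fnta-1 were not. The bound array on I was that of ints-8, where the summit was also 3 bp from rpr-1. The array in taf-1 that starts at I 13883899 has 39 copies and no region of the pooled list. Of arrays with at least 9 copies within 300 bp, all 6 on IV and 0 of 4 on I had a summit. The repeat and these array counts were chosen after the data were seen.

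**Figure D2:**
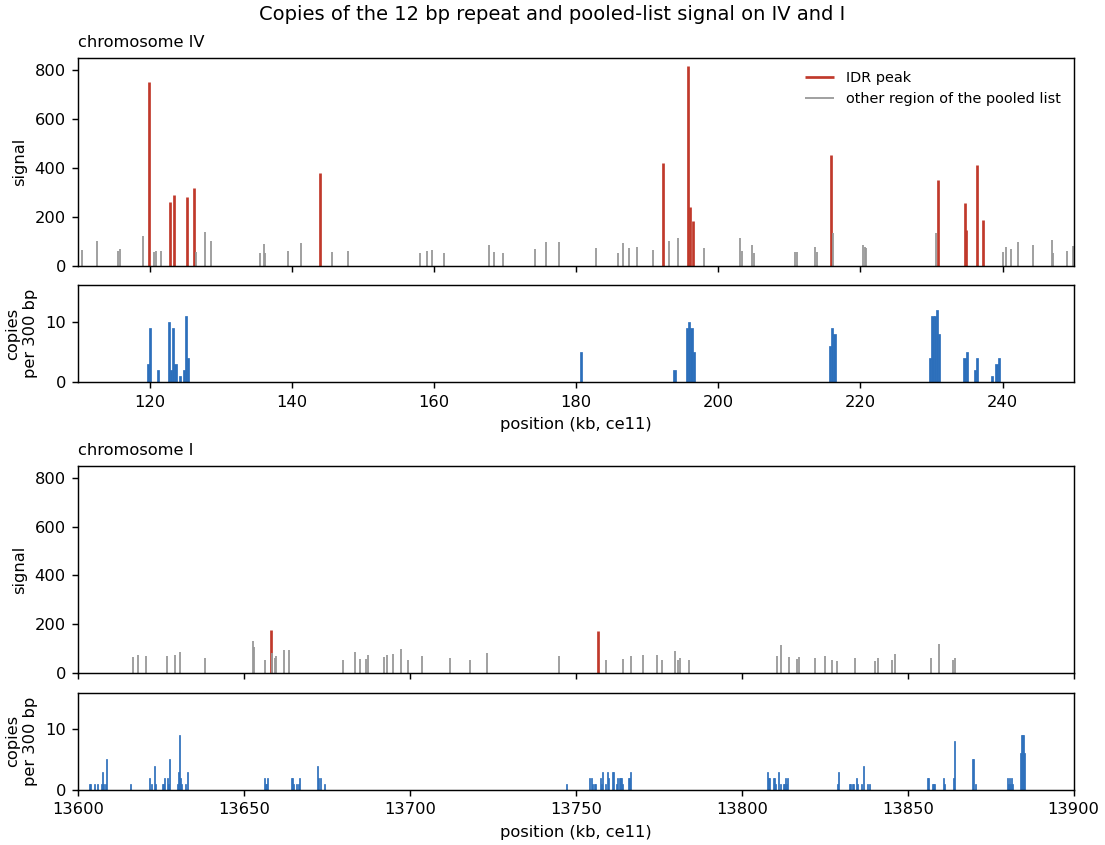
Signal (the authors' value) of regions of the pooled list and copies of the 12 bp repeat per 300 bp, against position (kb, ce11), for the left end of IV and part of the right arm of I, whose panel covers a longer stretch; red lines are IDR peaks and grey lines other regions. Of the arrays on IV 7 of 9 had an IDR summit, with signals up to 818.0, and of those on I 1 of 74. That array on I, in ints-8, lies outside the panel.

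The gene context of the peaks centred on small RNA genes and promoters. Of the 906 summits, 216 (23.8%, 95% interval 21.1 to 26.8) were within 500 bp of a tRNA gene, against 0.588% of placed positions, 40.5 times as many. snoRNA genes were near 72 summits (7.95% against 0.375%), snRNA genes near 16 (1.77% against 0.124%) and miRNA genes near 8 (0.883% against 0.263%). Promoters of protein-coding genes held 280 summits, 30.9% against 18.4%. Other exons (15.2% against 22.5%) and introns (23.3% against 29.3%) held fewer summits than placed positions, as did the surroundings of piRNA genes (2.43% against 4.55%) and pseudogenes (2.21% against 4.67%). The adjusted p from these placements was 0.00311, the smallest possible, for each of these classes except miRNA genes (0.0196). Intergenic sequence (30.6% against 29.7%), lincRNA and antisense RNA genes did not pass the test, and no summit was near an rRNA gene. Some of these results depended on the comparison with uniform placement. Against 15000 lower-ranked regions of the pooled list, a comparison chosen after the data were seen, the deficit in introns did not pass (23.98% in those regions, Fisher's exact adjusted p = 0.749). The share near piRNA genes was on the other side (2.02%, Fisher's exact adjusted p = 0.554), and intergenic sequence held more summits (20.8%, Fisher's exact adjusted p = 5.4e-11). The heterogeneous ncRNA biotype was near 261 summits (28.8% against 6.82%), of which 173 were also near a tRNA, snoRNA or snRNA gene.

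Counted by gene, 255 of 612 tRNA genes (41.7%) had a summit within 500 bp, against 1.03% expected from placed positions, as did 73 of 346 snoRNA genes (21.1%) and 15 of 129 snRNA genes (11.6%). Summits near tRNA genes were centred on the gene, with a median position 31 bp downstream of its start, where the median tRNA gene is 72 bp long, and 53.2% of the 216 lay inside the gene. Summits near snoRNA genes had a median position 29 bp upstream of the start, and 48 of the 72 were upstream. On X, 131 of 276 tRNA genes (47.5%) had a summit, against 124 of 336 (36.9%) on the other chromosomes together (Fisher's exact p = 0.0106, unadjusted). This comparison was not among those fixed beforehand. Neighbouring tRNA genes can share a summit, and the 131 genes on X lay near 106 summits, so the genes are not independent. X did not stand apart from each of them, since III had 46.9% and IV 40.8%, while V had 28.2%. The median signal was 193.5 for the 302 summits near tRNA, snoRNA or snRNA genes and 169.6 for the others. Many tRNA genes are identical copies, among which the assignment of reads by the authors is not given in the sources used here.

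**Figure D3:**
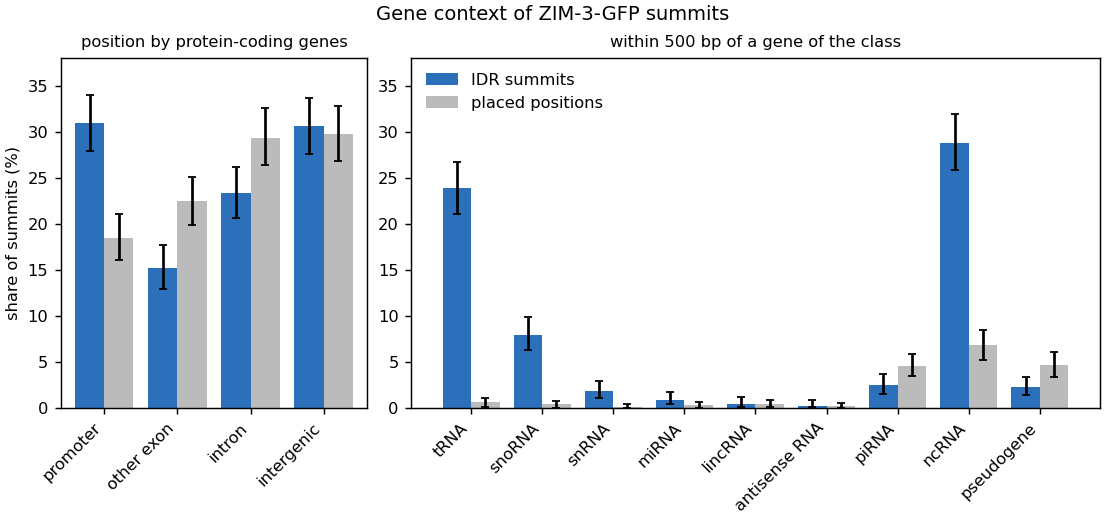
Share (%) of the 906 IDR summits (blue, with 95% binomial intervals) and of uniformly placed positions (grey, mean and central 95% of 1000 placements) by position relative to protein-coding genes (left) and within 500 bp of genes of each other class (right). Summits near tRNA genes reached 23.8% against 0.588% of placed positions, and promoters 30.9% against 18.4%.

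Genes of cytosolic ribosomal proteins, the respiratory chain and the chaperones were found near summits more often than other protein-coding genes. Without an untagged sample, differences between gene lists cannot be told apart from signal that any immunoprecipitation may give at highly transcribed sites. A summit lay within 1 kb of the start of 500 of 19973 protein-coding genes (2.50%). Cytosolic ribosomal protein genes had one in 23 of 80 cases (28.8%, odds ratio 16.4, Fisher's exact adjusted p = 1.5e-17). The highest were rpl-3 (signal 648.1), rps-26 (454.1), rpl-15 (358.2) and rpl-27 (328.8). The summit of rps-26 is that named above for tmem-107. That of rpl-27 was 714 bp from its start, past the other end of the gene. It was 64 bp upstream of egl-30, the nearest gene, looked up after the peak was seen. Genes of the mitochondrial respiratory chain and ATP synthase had a summit in 12 of 54 cases (22.2%, odds ratio 11.4, Fisher's exact adjusted p = 3.3e-08), led by the cytochrome c oxidase genes cox-6C (315.7), cox-6A (263.7), cox-5A (238.6) and cox-5B (219.6). Without replicate 1 the share of this list fell to 9.26% (Fisher's exact adjusted p = 0.0325, the highest over the alternatives, with 2.1e-08 the lowest). The cox-6C summit, at IV 126302, is one of the 20 in the dense window of IV, and the cox-6A summit lay in an snRNA-class gene. The list of heat shock protein and chaperonin genes had one in 10 of 59 (16.9%, odds ratio 8.09, Fisher's exact adjusted p = 7.0e-06). The highest within the list were hsp-1 (347.1), hsp-60 (325.4), dnj-13 (279.1) and hsp-3 (246.2). F44E5.4, the Hsp70 family gene named above (558.7), is not among the genes of this list.

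Splicing factors (5 of 46, Fisher's exact adjusted p = 0.018) and translation factors (4 of 40, adjusted p = 0.0473) passed with smaller margins. Their highest members were prp-19 (236.6) and snrp-200 (233.4), then snr-1 and snr-6, and iff-2 (194.7), the elongation factor genes eef-2 (174.0) and eef-1A.1, and eif-2Bgamma. No summit of replicate 2 was matched to that of iff-2, and the snr-6 summit was matched only at rank 10042 of replicate 1. The summits of snr-1 and snr-6 were 985 bp and 623 bp from the starts, past the opposite ends of these genes. The translation factor list no longer passed without either replicate, and the splicing factor list not without replicate 1, where 1 of 40 and 3 of 46 genes had a summit. With summits within 500 bp of the start, the splicing factor share was 2.17% (Fisher's exact adjusted p = 0.772). Seven-transmembrane chemoreceptor genes, a family expressed mainly in sensory neurons, had a summit less often than other genes, in 5 of 1364 cases (odds ratio 0.135, Fisher's exact adjusted p = 2.6e-09). The summits of sre-23 and srh-269 were 67 bp from a snoRNA gene and 19 bp from a tRNA gene. srw-85 and srh-2 had signals of 176.4 and 170.0. The list of tRNA, snRNA, snoRNA, rRNA and microRNA genes had summits in 388 of 1368 genes (odds ratio 17.5, Fisher's exact adjusted p = 1.6e-273), with the snoRNA genes ZK994.7, C51F7.3 and C51F7.4 and a neighbouring tRNA gene the highest.

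Germline and tissue lists did not pass. Meiotic pairing, synapsis and recombination genes had a summit in 1 of 52 cases, brd-1 (signal 145.2), where a tRNA gene was 13 bp away. Among germ granule and small RNA factors 1 of 29 had one, ego-1 (414.6), an RNA-dependent RNA polymerase gene. Histone genes had summits in 5 of 81 cases (Fisher's exact adjusted p = 0.125), with his-59 and his-60 sharing a single summit, and htz-1 and his-67 following. Major sperm protein (0 of 54), body wall muscle (0 of 40) and yolk protein genes (0 of 6) had none. Cuticle collagens (6 of 180, with col-85, col-42, col-63 and col-185), intestinal genes (asp-1 and cpr-1, 2 of 35), neuronal genes (unc-25, 1 of 38), proteasome subunits (pas-5, 1 of 33), nuclear hormone receptors (nhr-255, nhr-68 and nhr-47, 3 of 269) and F-box genes (fbxb-72, fbxb-85 and fbxa-83, 3 of 322) did not pass either (adjusted p from 0.149 to 0.723). Neighbouring genes can share a summit, which these tests count as separate genes.

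**Figure D4:**
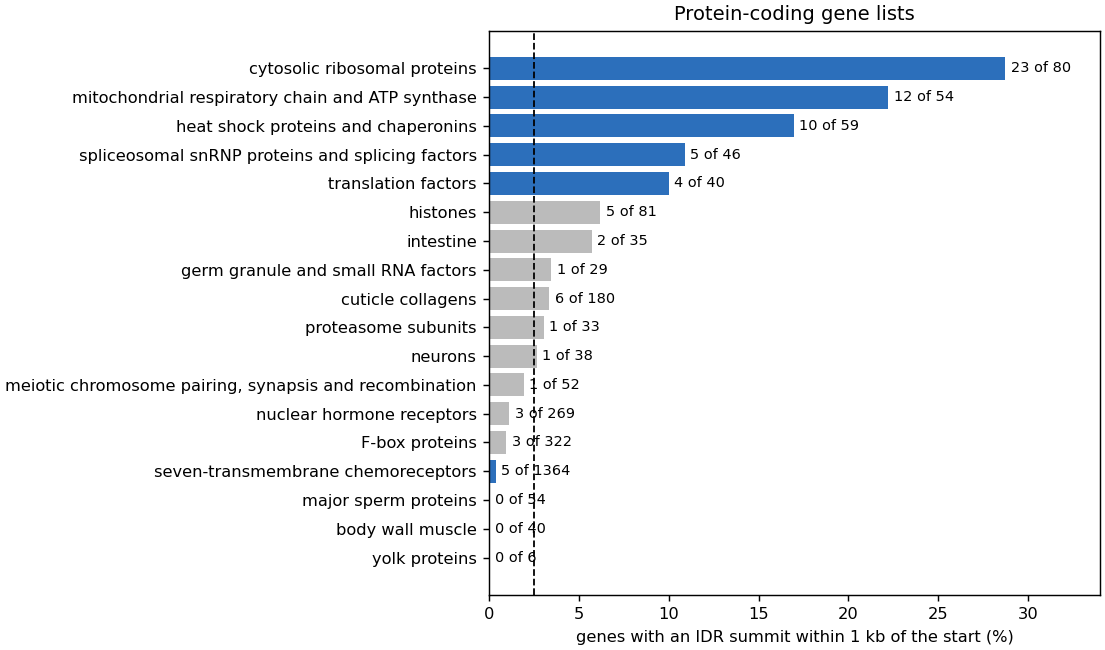
Share (%) of the genes of each protein-coding list with an IDR summit within 1 kb of the start, with counts beside the bars; blue bars passed Fisher's exact test after adjustment and the dashed line is the 2.50% of all protein-coding genes. Ribosomal protein genes stood at 28.8% and chemoreceptor genes at 0.367%.

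The locus of the tagged gene did not itself carry an IDR peak. Within 1 kb of zim-3, at IV 10558715 to 10561429, the highest region of the pooled list had a signal of 104.2 and rank 2902. The neighbouring paralogs him-8 and zim-1, which encode the pairing centre proteins of other chromosomes, reached signals of 80.6 (rank 8237) and 67.3 (rank 15090), and zim-2 had no region. unc-119 on III, the marker gene mutated in the strain, had no region within 1 kb. The nearest IDR summit to zim-3 was 12006 bp away, at IV 10573435.

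The replicates shared their strongest sites and differed further down. All 906 IDR peaks had a summit of replicate 1 within 200 bp and 894 (98.7%) one of replicate 2. These peaks were the highest of a list called on the pooled reads of the same replicates, so this match is not independent of how they were selected. Of the 906 highest regions of replicate 1, 498 (55.0%) were matched among the 906 highest of replicate 2, against 0.362% by chance. The 100 highest regions of replicate 1 were all matched in the list of replicate 2, at a median rank of 60.5, while 34.7% of those ranked 20001 to 30000 were, where uniform placement gives about 12%. Over the 894 peaks matched in both, the signals had a Spearman correlation of 0.451 (bootstrap 95% interval 0.389 to 0.515), across peaks that are not independent replicates and were selected on the pooled reads. The signal in replicate 1 was a median 2.76 times that in replicate 2, on scales that the authors' processing sets separately.

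**Figure D5:**
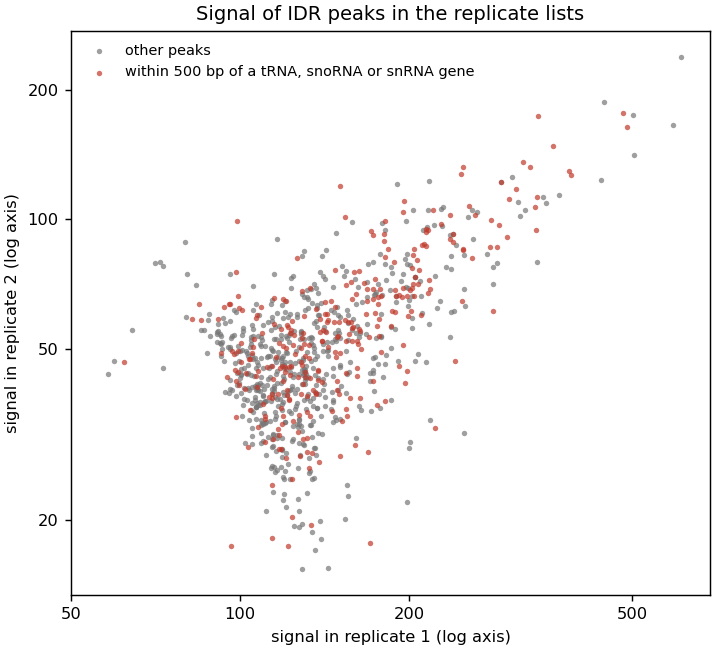
Signal (the authors' value, log axes) of the 894 IDR peaks with a summit within 200 bp in the lists of both replicates; red points lie within 500 bp of a tRNA, snoRNA or snRNA gene. The Spearman correlation across peaks was 0.451, and the highest signals of one replicate were also high in the other.

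Summits with the 5 leading 8-mers lay mostly near tRNA genes. GGGTTCGA, part of the conserved T arm of tRNA genes, was present within 50 bp of 57 of 906 summits (6.29%) and in 9 of 1812 flanking windows (0.497%; Fisher's exact test, adjusted p = 7.6e-15). CTGAGCTA (4.97% against 0.166%), AGTGGTTA (4.42% against 0.11%), ATCGAACC (4.19% against 0.11%) and GCTCTACC (4.08% against 0.11%) followed. Of the summits with each of these 5 sequences, 80.0% to 95.6% were within 500 bp of a tRNA gene. Many tRNA genes are identical copies, and each flank belongs to a tested summit. The windows are therefore not independent, and the 8-mer tests describe this peak list. In all, 363 8-mers were more frequent at summits and 162 less frequent, the latter led by A-rich sequences such as AAAAAAAT (3.09% against 12.1%). Summit windows had 47.3% G and C against 36.5% in the flanks. On I and IV alone, 2 8-mers were more frequent, GGGTTCGA and AGTGGTTA, and on the other chromosomes 152. Fewer summits entered the test on I and IV (279 against 627), and the difference between the chromosome sets was not tested.

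None of the 5 leading 8-mers was concentrated on I or IV in the way of the 12 bp repeat. GGGTTCGA occurred 1976 times, most densely on V (26.6 per Mb), CTGAGCTA and AGTGGTTA most densely on X (22.5 and 24.8 per Mb) and ATCGAACC on III (23.7 per Mb). GCTCTACC was densest on I (13.4 per Mb), where its excess over the genome mean ranked above only 20.3% of 8-mers of the same base composition. The corresponding percentiles were 96.5 for CTGAGCTA, 96.2 for AGTGGTTA, 90.6 for GGGTTCGA and 74.7 for ATCGAACC. The densest 500 kb windows lay on V, X or III for all 5.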

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

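The comparisons without summits near tRNA, snoRNA or snRNA genes, against lower-ranked regions of the pooled list and on repeat arrays were chosen after the data were seen, and the other alternatives before. The excess of summits in promoters and near tRNA, snoRNA and snRNA genes, the excess at ribosomal protein, respiratory chain and chaperone genes and the deficit at chemoreceptor genes kept their direction and side of the threshold under each alternative run on them, although the share of respiratory chain genes fell from 22.2% to 9.26% without replicate 1. Against lower-ranked regions the deficit in introns was lost and the share near piRNA genes lay on the other side. The highest regions of the pooled list were by construction the same 906 peaks. Results that need an annotation or chromosome lengths were not run on ce10. The causes of the changes that follow were not tested except where stated.

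With one replicate left out, the share on I and IV lay between 31.9% and 32.8%, the higher value, from replicate 2 alone, above the share of length. The difference in median signal between I and IV and the others was -0.889 in the list of replicate 2 and 1.37 in that of replicate 1, each on its own scale, so only the directions compare. The number of ends past the threshold lay between 1 and 2, as did that of windows, with the left end and the window of IV called each time (ratios 1.91 and 2.05, and 20 and 22 summits). Both were also called in the higher-signal peaks (1 end and 1 window in all), and without summits near small RNA genes 1 end was called. Joining summits within 10 kb left the ratio at the left end of IV at 1.41, 9 summits in its densest window (placed median 9), 0 ends and 0 windows, while X passed at 21.1%. The deficit at the left end of II no longer passed its test without replicate 2 (ratio 0.477), in the higher-signal peaks (0.314) and without summits near small RNA genes (0.428). Nor did it pass with joined summits (0.344) or with 1 Mb ends (0.316). Each of these ratios was still a deficit. Ends of 1 Mb gave 1 call and of 3 Mb 4 calls, and 1 Mb windows gave 1. The ratio at the left end of IV was 2.99 in the higher-signal peaks and 3.21 with 1 Mb ends, its highest over the alternatives, where joined summits gave the lowest. The share of X was 13.1% without summits near small RNA genes, below its length. The gene lists past the threshold numbered 5 to 8 against 7, and translation factors were lost in 6 of 8 alternatives, splicing factors in 3. Histones were gained in 3 and F-box genes in 2, and neurons with gene bodies counted.

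Matching within 50 bp gave 80.4% of IDR peaks in replicate 2 and 39.3% shared among the highest regions, within 500 bp 99.6% of IDR peaks, and by reciprocal overlap 96.9%. The share was 62.3% for the upper 453 regions and 46.8% for 1812. The 8-mers more and less frequent at summits numbered 103 and 28 for the higher-signal peaks, 863 and 310 within 100 bp, 13 and 35 without summits near small RNA genes, and 180 and 0 against shuffled windows, which keep the base composition of the summits. With k of 6 there were 284 less frequent sequences, and with k of 10 there were 174 more and 6 less frequent. Read depth, which would limit the lower-ranked regions, is unknown.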

Other observations

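The tests on the repeat arrays were chosen after the result was seen, except that on other tandem repeats. The tests of explanations for the summits near tRNA genes and for chromosomes III and V were set before their results were seen.

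The copies of the 12 bp repeat differed in their surroundings between the chromosomes. A T preceded the core in 182 of 188 copies (96.8%) in the first Mb of IV and in 330 of 797 (41.4%) on I beyond 10 Mb. The core was chosen at summits on IV and, between tied 12-mers, for its copy number in the genome. This contrast may therefore follow in part from the choice of the core. Arrays on IV had a median of 11 copies in their densest 300 bp and those on I a median of 3. The bound arrays on IV with the most copies were those of gtf-2H1 (46) and grld-1 (42), and the array of csn-3 had 33. Over the span of the 74 arrays on I, 29 regions of the pooled list were found where 49.5 would fall by uniform placement.

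Sites near tRNA genes were shared unevenly among the chromosomes. On X 106 of the 186 summits (57.0%) were within 500 bp of a tRNA gene, against 11.7% to 19.05% of the summits on each other chromosome. The tRNA genes of V had the lowest share with a summit (28.2%) and those of X (47.5%) and III (46.9%) the highest. Outside small RNA genes, 13 8-mers were more frequent at summits, led by GAGCGCGC, and 35 less frequent.

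Arrays of the repeat at the left end of IV carried IDR summits and those on the right arm of I, the other chromosome whose pairing centre ZIM-3 serves, with the exception of ints-8, did not when summits were taken within 300 bp (within 1 kb, 4 of the 74 on I did). The repeat was chosen for its presence at summits on IV, which sets most of that side of the contrast. Loss of reads that cannot be placed uniquely on I is argued against for the arrays on I as a set. Their median share of 31-mers found once in the genome was 95.4%, against 72.8% on IV. It was taken over whole arrays with their edges, so it includes the sequence between copies, which is longer on I. The 4 arrays on I with at least 9 copies within 300 bp are too few to decide. They had 25.6% (taf-1, 39 copies), 71.9%, 78.7% and 85.6%, where the 6 such arrays on IV ran from 37.0% to 87.5%. For tandem repeats in general, 12 of 2008 stretches with at least 6 copies of another 12-mer within 300 bp had an IDR summit (0.598%, 95% interval 0.309 to 1.04). Uniform placement gives about 0.865% for a stretch of median length. How uniquely reads can be placed in these stretches was not measured, so a tendency of tandem repeats to form peaks stays open. A need for dense copies preceded by T may contribute and stays open, because only 1 array on I has at least 9 such copies within 300 bp, and it had no summit (Fisher's exact p = 0.143 against IV, with too few arrays to decide and the arrays on IV chosen with the repeat). No biological explanation was tested, since the study has a single group.

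The excess of summits near tRNA, snoRNA and snRNA genes was set against 3 technical explanations for the tRNA part. For reads shared between copies, tRNA genes whose whole sequence occurs once had a summit in 32.1% of cases (45 of 140, 95% interval 24.5 to 40.6). Placed positions gave 1.04%. Such genes can still closely resemble other copies, and the summit may lie at a neighbouring tRNA gene within 500 bp. This explanation therefore stays open. Neighbouring protein-coding promoters are argued against, because 41.1% of tRNA genes over 1 kb from every protein-coding start had a summit. The GC content under the summits is argued against, because positions of matched GC content were near a tRNA gene in 0.861% of cases, at most 1.66% in 100 draws, against 23.8% of summits. Signal that any immunoprecipitation may give at highly transcribed sites stays open, since no untagged sample was analysed here, and the study has no second group for a biological explanation. The same limit applies to the promoters and the protein-coding gene lists.

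Chromosome III held more and V fewer summits than their lengths give, and an uneven spread of tRNA, snoRNA and snRNA genes could produce this. Without summits near such genes the ratio to length was 1.54 on III (exact binomial p = 5.9e-07) and 0.762 on V (p = 0.00223). These genes therefore do not account for the excess on III. For V they do not account for the whole deficit but may hold part of it. The ratio on V was 0.682 over all summits and 0.524 among the summits near such genes. For X they change the direction, with a ratio of 1.16 over all summits and 0.740 without those near such genes. Other features of the chromosomes, such as gene density, were not tested.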
